A study of Mus musculus with 6 samples.

How the data were processed

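RNA was measured in 6 libraries of mouse oocytes, 3 WT and 3 Khdc3-null, and each library was assigned to its group and replicate by its title. Per the labels' protocols, oocytes were dissected by hand from ovaries, RNA was isolated with a PicoPure kit and libraries were made with the NEB Ultra II Directional kit, which keeps the strand of origin. Whether reads were counted by strand is not given in the sources used here, so antisense and overlapping genes may share reads. Per the submitters' processing notes, FastQC 0.11.7, STAR 2.6.0c and featureCounts 1.6.2 were used with the genome build GRCm38.p6. The authors deposited 1 table of RPKM values (reads per kilobase of gene length, scaled to library depth) for 53656 gene symbols, of which 19437 were at 0 in all libraries. Its columns carry numbers that match the description of 1 sample each.

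Gene symbols were matched to GENCODE M21 (GRCm38), 28452 by symbol and 250 by an older symbol. Of the 12272 tested genes, 10285 (83.8%) were matched and have coordinates, and 1951 of the others carry clone-based names. Read depth was recovered from the RPKM values: with exon-union lengths from GENCODE M21, 92.4% of 19865 matched genes with reads gave whole reads in all 6 libraries at a tolerance of 0.01. For the other tested genes the smallest length that gives whole reads was used, 2885 genes in all, so their read numbers may be too low by a common factor. The library totals so obtained were 34640170 to 43343444 reads, and tested genes held 98.8% to 99.0% of them.

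Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior), with genotype as the only covariate, for genes with an RPKM of 1 or more in at least 3 of 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. A fold change is on the log2(RPKM + 1) scale, which understates the change of low genes. Gene lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over 34 lists. Of 35 lists fixed beforehand, 1 had no tested member. With camera 6 lists passed, all of them higher in KO. With an estimated correlation 0 passed (lowest adjusted p 0.81). In fry 0 passed for a shift in 1 direction and 20 for change in either direction. Genes near Khdc3 were tested with Fisher's exact test, and list means and single values with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p under 0.1. Positions of called genes were compared with 10000 random draws of tested genes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9.

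The groups, the design, the gene lists, the rule for named genes and all alternatives but 1 were set before the data were examined. Named genes are Khdc3, the members of the subcortical maternal complex list, the 12 genes with the largest change in each direction among called genes whose groups do not overlap, and up to 3 members of each list with the smallest p (with fewer than 12 in a direction, all would be named, filled up to 5 by the smallest p). Predicted genes and pseudogenes were skipped when choosing the 12, and clone-based names were treated as predicted genes after the table was seen. Genes outside this rule are said in the text to be chosen after their values were seen, and the tests of positions along chromosomes were also chosen after the calls were seen. Fold changes of tubulin and other genes with near-identical copies are uncertain.

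The fit was tested on simulated reads for the KO and WT comparison, with 12105 genes in the fit and 200 genes drawn to change by 1.5, 2 or 4-fold. It called 81.0% of 58 genes changed 1.5-fold, 71 of 71 changed 2-fold and 64 of 64 changed 4-fold, with 12 calls among 11912 unchanged genes and 0 calls where nothing was changed. The simulation drew every gene on its own with the same dispersion (0.0086) and without a library that stands apart. These rates hold for that setting and may be better than in the real libraries. As a check for a library entered more than once, libraries of a genotype were compared, and every pair differed by more than counting noise (lowest chi-square per degree of freedom 16.1). This does not show that they came from separate animals. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of RPKM 5, 3 rescalings, the replicate number as a block, library weights, a robust prior, other thresholds, other windows around Khdc3, each library left out in turn, and limma voom on the recovered reads, which was added after seeing that the values fall on whole reads. The labels name no sequencing batch or date. The results of some genes that the rule names are not reported here.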

Results

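RNA of mouse oocytes dissected by hand from ovaries was sequenced in 6 libraries, 3 wild-type (WT) and 3 Khdc3-null (KO). Khdc3 (also known as Filia) encodes a protein of the subcortical maternal complex, an assembly of maternal proteins at the cortex of the egg and early embryo. The comparison asked how the oocyte transcriptome differs when the gene is lost. Expression was given as RPKM for 53656 gene symbols, and 12272 genes with an RPKM of 1 or more in at least 3 of the 6 libraries were tested. The RPKM values corresponded to library totals of 34640170 reads in WT replicate 1, 40628920 in WT replicate 2, 40417493 in WT replicate 3, 39250135 in KO replicate 1, 40394363 in KO replicate 2 and 43343444 in KO replicate 3. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. Pearson correlations of log2(RPKM + 1) across tested genes were 0.985 to 0.991 within a genotype and 0.974 to 0.981 between genotypes, and genes are not independent replicates. KO replicate 1 stood apart from the other KO libraries on the second principal component, which held 18.1% of the variance, while the first (49.5%) separated the genotypes.

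Khdc3 (ENSMUSG00000092622.8, chromosome 9, 73101836 to 73104438, plus strand, GRCm38, protein coding) was close to absent from all 3 KO libraries. Its level was 423, 425 and 502 RPKM in WT replicates 1, 2 and 3, a mean of 450 ± 45.1 RPKM (SD, n = 3) that ranked 75 among all genes in WT. In KO replicates 1, 2 and 3 it was 0.224, 0.217 and 0.113 RPKM, a mean of 0.185 ± 0.0624 RPKM (SD, n = 3), or 0.041% of the WT mean. These levels rest on 18, 18 and 10 reads in the KO libraries and on 30025, 35398 and 41594 reads in the WT libraries. The change on the log2(RPKM + 1) scale was -8.57 ± 0.09 (SE; limma, adjusted p = 1.8e-09), and the exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 allow. The level of the targeted gene matched the genotype label in all 6 libraries.

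Beyond Khdc3, transcripts above 10 RPKM in WT and below 1 RPKM in KO included Gsto2, a glutathione S-transferase of the omega class, Tmem87a, Cfap58 and Batf3, a transcription factor of the AP-1 family. Transcripts higher in KO included Slc14a1, a urea transporter, Kcnh1, a voltage-gated potassium channel, Lyplal1 and Usp3, a deubiquitinase. In all, 336 of 12272 tested genes passed an adjusted p of 0.05 (limma), of which 196 were higher and 140 lower in KO, and 92 of them changed at least 2-fold (54 higher, 38 lower). All 336 had 3 KO values outside the range of the 3 WT values. Of all tested genes 25.8% were separated in this way, where chance gives 10% on average. Genes vary together between libraries, so the share in 1 division of the libraries can lie far from that average. The shares in other divisions were not computed. Predicted genes, clone-named genes and pseudogenes made up 88 of the 336 and are counted without being named.

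Gsto2 (chromosome 19, 47865534 to 47886324) fell from 41.4 ± 18.9 to 0.142 ± 0.155 RPKM (SD, n = 3 each), a log2 change of -5.14 ± 0.27 (SE; limma, adjusted p = 5.8e-05). Cfap58, its neighbour, fell from 12.4 ± 4.41 to 0.934 ± 0.104 RPKM. Both genes also varied between the WT libraries and were highest in WT replicate 1. In WT replicates 1, 2 and 3, Gsto2 stood at 63.26, 29.98 and 31.01 RPKM and Cfap58 at 17.48, 9.95 and 9.74 RPKM. Tmem87a (chromosome 2, 120355312 to 120404113) fell from 14.9 ± 5.01 to 0.377 ± 0.170 RPKM, with a log2 change of -3.48 ± 0.24 (SE; adjusted p = 2.7e-04). On the same chromosome, the cytosolic phospholipase A2 genes Pla2g4f and Pla2g4e fell by 2.25 and 1.77 on the log2 scale. Batf3 fell by 2.68, Rttn, a gene needed for centriole assembly, by 2.37, Fam132a by 2.08, Ttc34 by 1.97, Susd4 by 1.87 and Klrb1 by 1.49. Rttn stood at 20.2 ± 2.79 RPKM in WT and 3.10 ± 0.453 RPKM in KO. Pla2g4e and Klrb1 lost their calls when no filter on low values was applied (adjusted p = 0.063 and 0.061).

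Slc14a1 (chromosome 18, 78100091 to 78142119) was listed at 0 in WT replicates 1 and 2 and at 0.0557 RPKM in WT replicate 3, against 13.3, 13.1 and 12.7 RPKM in KO replicates 1, 2 and 3 (limma, adjusted p = 5.8e-07). Kcnh1 (chromosome 1, 192190774 to 192510159) rose from 11.1 ± 0.618 to 42.4 ± 0.435 RPKM (SD, n = 3 each), a log2 change of 1.85 ± 0.07 (SE; adjusted p = 8.4e-06). Lyplal1, on the same chromosome, rose from 14.4 ± 1.73 to 49.8 ± 5.25 RPKM and Usp3 from 9.01 ± 0.705 to 28.3 ± 2.38 RPKM. The tubulin gene Tuba3b rose from 15.9 ± 4.93 to 58.2 ± 6.74 RPKM, although tubulin genes resemble one another closely and their reads may not be assigned with certainty. March11, Coro2b, Plbd1, Aldh1a1, a retinaldehyde dehydrogenase, Slc43a3 and Vps13a were also among the 12 largest rises, with log2 changes of 2.21, 1.76, 1.72, 1.67, 1.65 and 1.46. Of these, Coro2b, Aldh1a1 and Vps13a lost their calls without WT replicate 3 (adjusted p = 0.051, 0.053 and 0.052), Vps13a also without KO replicate 3 (0.057), and Plbd1 without WT replicate 2, KO replicate 2 or KO replicate 3 (0.056, 0.064 and 0.068). All 4 also missed the threshold with no filter on low values (0.092, 0.087, 0.092 and 0.107 in the order Coro2b, Aldh1a1, Vps13a and Plbd1).

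**Figure D1:**
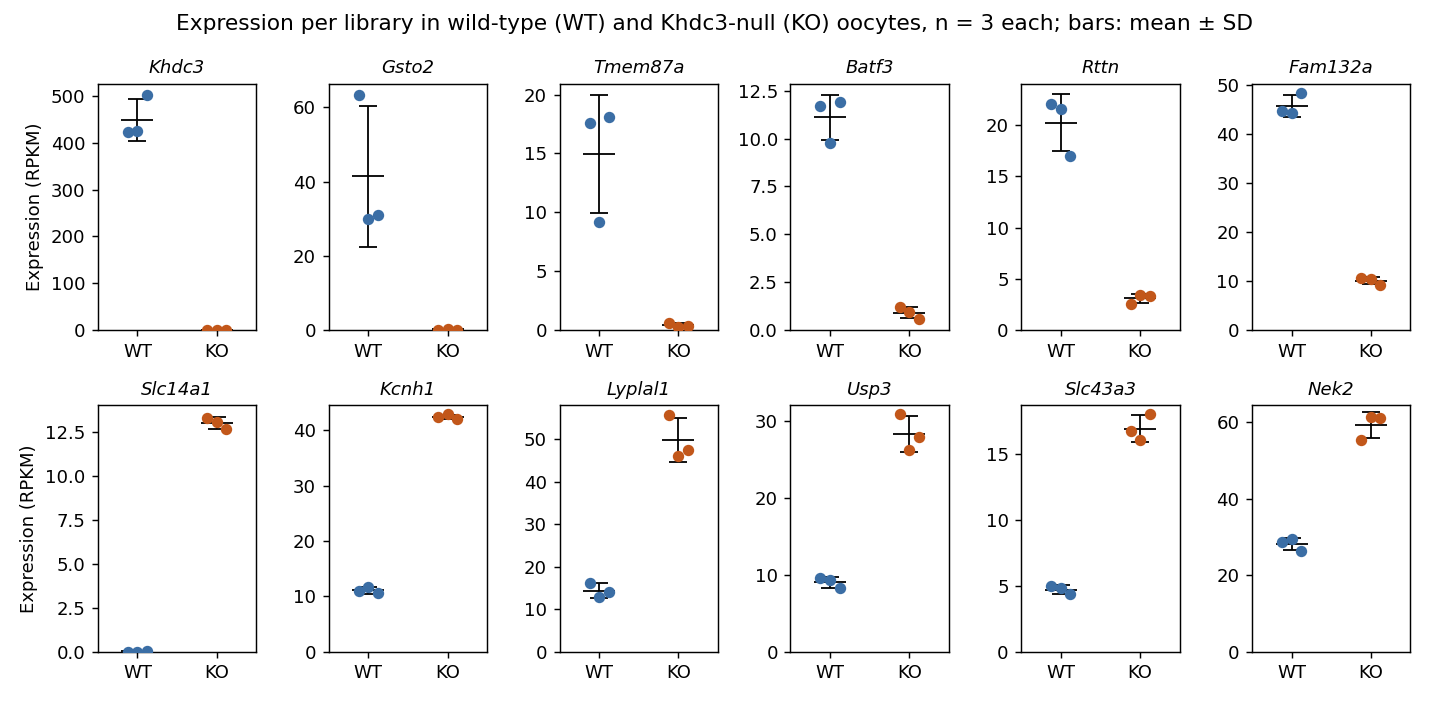
Expression (RPKM, linear axes from 0) of 12 genes in each of 3 wild-type (blue) and 3 Khdc3-null (orange) oocyte libraries, with the mean ± SD (Nek2 was chosen after its values were seen). Khdc3 stands at 423 to 502 RPKM in wild type and at 0.113 to 0.224 RPKM in the knockout.

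The count of 336 was sensitive to single libraries. It was 195 without WT replicate 2, 161 without WT replicate 3, 152 without KO replicate 2, 151 without KO replicate 3 and 289 without KO replicate 1, the library that stood apart, where 138 were higher and 151 lower. With no filter on low values 94 genes were called, and among the list members described next Astl, Spc25, Pdk1, Akt1, Gabarap, mt-Nd5, mt-Nd1, Nr5a1, Acta2, Fos and Egr1 then lost their calls (adjusted p of 0.051 for Gabarap to 0.173 for mt-Nd1).

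None of the 12 members of the subcortical maternal complex list besides Khdc3, all of them tested, passed the threshold, over all genes or adjusted over the list alone. Padi6, the peptidylarginine deiminase of the oocyte's cytoplasmic lattices, stood at 3135 ± 83.3 RPKM in WT and 2660 ± 249 RPKM in KO (SD, n = 3 each; log2 change -0.24 ± 0.08, SE; adjusted p = 0.16). Nlrp5, also known as Mater, stood at 572 ± 36.0 and 491 ± 104 RPKM (adjusted p = 0.42), Ooep at 686 ± 138 and 610 ± 45.8 RPKM (0.60) and Tle6 at 970 ± 36.8 and 925 ± 4.52 RPKM (0.56). Of the 12 members, 11 had a negative change. The mean log2(RPKM + 1) of the list was 8.964 ± 0.0289 in WT and 8.856 ± 0.0297 in KO (SD over libraries, n = 3 each). Every KO library lay below every WT library (exact permutation p = 0.1, the smallest possible). The list as a whole, with a median log2 change of -0.11, missed the threshold (camera adjusted p = 0.078). It passed with no filter on low values (0.025), without KO replicate 3 (0.031) and on the recovered reads (0.046), and its adjusted p was 0.81 with an estimated correlation.

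Among the other oocyte lists, few members changed. Astl, which encodes the protease that cleaves the zona pellucida after fertilisation, was the 1 gene to pass of 24 oocyte growth and zona pellucida genes, and fell from 717 ± 100 to 451 ± 51.5 RPKM (log2 change -0.67 ± 0.12, SE; limma adjusted p = 0.031). Patl2, an RNA-binding protein of growing oocytes, fell by 0.44 on the log2 scale and was the 1 gene called of 26 in maternal mRNA storage, translation and decay. Exd1, a factor of the piRNA pathway, fell from 24.0 ± 3.88 to 9.19 ± 0.653 RPKM and was the 1 called of 27 small RNA pathway genes. Patl2 and Exd1 lie in different groups of called genes on chromosome 2, among the groups described below. Spc25, a kinetochore component, rose by a log2 change of 0.44 as the 1 called of 41 spindle genes, Rad51d, a factor in homologous recombination, by 0.90 as the 1 of 44 DNA damage genes, and Rnh1, the ribonuclease inhibitor, by 0.68 as the 1 of 16 tRNA genes. No member passed among 27 maternal-effect, 22 DNA methylation, 31 histone modification, 17 imprinted or 19 p53 and apoptosis genes. Adjusted over the list alone, the 6 genes above passed in their lists, and so did the imprinted gene Nnat (log2 change 0.65, adjusted p over all genes 0.064). None of these lists passed camera (lowest adjusted p 0.17). Astl lost its call without WT replicate 1 or 3 and without each KO library in turn (adjusted p = 0.082, 0.090, 0.057, 0.062 and 0.081), and Spc25 without WT replicate 2 or 3 and without each KO library in turn (0.118, 0.102, 0.061, 0.066 and 0.107).

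Among genes of sterol and lipid handling, Sc5d, which acts near the end of cholesterol synthesis, rose from 8.76 ± 0.546 to 21.7 ± 4.51 RPKM (SD, n = 3 each; log2 change 1.20 ± 0.13, SE; limma adjusted p = 0.0036). Of the 23 tested genes of the cholesterol synthesis list, 1 was called higher and 1 lower. Adjusted over the list alone, 2 were higher, the other being Sqle, squalene epoxidase, with a log2 change of 0.37, and 1 was lower. The list itself did not pass camera (adjusted p = 0.67). Of 22 lipid uptake, storage and transport genes, 18 had a positive change and Npc1, which exports cholesterol from lysosomes, was called, rising from 3.79 ± 0.0738 to 8.44 ± 0.333 RPKM (log2 change 0.98 ± 0.08, SE; adjusted p = 6.2e-04). Npc1 lies in a group of 3 called genes on chromosome 18, 1 of the groups along the chromosomes described below. Adjusted over the list alone, 3 members were higher, the others being Plin2, a lipid droplet coat protein, and Fabp5, with log2 changes of 0.35 and 0.31. The list passed camera (adjusted p = 0.035; adjusted p = 0.81 with an estimated correlation), with a median log2 change of 0.17. Its mean was higher in all 3 KO libraries than in all 3 WT libraries, as were the means of the granulosa and the stromal marker lists. The lipid list missed the threshold without WT replicate 2 (0.054), WT replicate 3 (0.061), KO replicate 2 (0.115) or KO replicate 3 (0.092) and with a filter of RPKM 5 (0.153).

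In other metabolic lists, Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by a log2 change of 0.64 as the 1 of 28 tricarboxylic acid cycle and pyruvate entry genes. The kinase gene Akt1 fell by 0.43 on the log2 scale as the 1 of 33 insulin and mTOR signalling genes, and Gabarap rose by 0.48 as the 1 of 26 autophagy and lysosome genes. In the fatty acid oxidation list 1 of 26 genes was called, and adjusted over the list alone 1 was higher. No member was called among 23 fatty acid synthesis, 22 glycolysis and glucose transport, 32 pentose phosphate and redox, 28 unfolded protein response or 14 interferon genes. Adjusted over the list alone, Pdk1, Akt1 and Gabarap passed, 3 glycolysis genes (among them Eno1 and Pfkl) were higher and 1 (Pfkm) lower, and Hspa8, a constitutive heat shock protein, and Tlr3 were higher, with log2 changes of 0.61 and 0.52. Over all genes, Hspa8 and Tlr3 narrowly missed the call (limma adjusted p = 0.052 and 0.053). Both were called with library weights (0.011 and 0.038) and with voom (0.028 and 0.016), and Hspa8 also without KO replicate 1 (0.016). None of these lists passed camera, except that with library weights the fatty acid oxidation (adjusted p = 0.033) and unfolded protein response (0.026) lists did. Without KO replicate 1, the fatty acid oxidation (adjusted p = 0.025), glycolysis (0.033), tricarboxylic acid cycle (0.042) and unfolded protein response (0.016) lists passed. With an estimated correlation and all libraries their adjusted p was 0.81, 0.85, 0.81 and 0.81. These 3 genes each lost their call in fits without some single libraries, with adjusted p up to 0.057 for Pdk1 without KO replicate 3, 0.086 for Akt1 without WT replicate 2 and 0.069 for Gabarap without WT replicate 3.

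Transcripts of the mitochondrial genome and of ribosomal protein genes lay higher in KO. All 14 mitochondrial transcripts had a positive change, with a median log2 change of 0.44. Of these, mt-Nd5 rose from 41.5 ± 3.27 to 65.9 ± 7.68 RPKM and mt-Nd1 from 179 ± 14.3 to 262 ± 37.7 RPKM (SD, n = 3 each; limma adjusted p = 0.016 and 0.043), and 11 passed when adjusted over the list alone. All 77 ribosomal protein genes had a positive change, with a median of 0.17, but none was called over all genes or over the list alone. The nuclear genes of oxidative phosphorylation were positive in 60 of 69, with a median of 0.12 and none called. The 3 lists passed camera (adjusted p = 6.5e-07, 5.4e-08 and 0.0011), and none did with an estimated correlation (adjusted p = 0.81, 0.81 and 0.82). KO replicate 1 was the highest library in all 3 lists. Without it the oxidative phosphorylation list no longer passed (0.172), and the medians of the mitochondrial and ribosomal lists were 0.31 and 0.07. Both mt-Nd5 and mt-Nd1 lost their calls in fits without some single libraries, with adjusted p of up to 0.058 without KO replicate 2 and 0.145 without WT replicate 2.

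Among markers of other ovarian cells, those of granulosa and of stroma were also higher in KO. The mean log2(RPKM + 1) of 20 granulosa and cumulus cell markers was 2.84 ± 0.28 in WT and 3.28 ± 0.15 in KO, and that of 14 markers of stroma, smooth muscle and surface epithelium was 1.98 ± 0.24 and 2.51 ± 0.23 (SD over libraries, n = 3 each; exact permutation p = 0.1 for each, the smallest possible). In both lists every KO library exceeded every WT library. Nr5a1, a transcription factor of steroidogenic cells, was called at 1.08 ± 0.131 against 2.74 ± 0.753 RPKM, and so was Acta2, smooth muscle actin, at 5.58 ± 0.865 against 10.2 ± 1.80 RPKM (limma adjusted p = 0.039 and 0.034). Adjusted over the list alone, 1 granulosa marker was higher, and 10 stromal markers were higher and 2 lower. Both lists passed camera (adjusted p = 0.0069 and 0.0052), and neither did with an estimated correlation (adjusted p = 0.81 for each). Theca and luteal (6 genes), endothelial (3), leukocyte (3) and erythroid (4) markers held no called gene and did not pass, although adjusted over the list alone Plvap and H2-Aa were higher and Tek lower. The granulosa list missed the threshold without WT replicate 3 (0.143) or KO replicate 3 (0.069), and the granulosa and the stromal list both did with a filter of RPKM 5 (0.153 and 0.580). The theca list passed without WT replicate 2 (camera adjusted p = 8.8e-06, and 0.81 with an estimated correlation and all libraries). WT replicate 2 held the highest theca mean of all libraries, 3.58, against 2.28 and 2.07 in WT replicates 1 and 3 and 3.22 to 3.54 in KO. Nr5a1 and Acta2 lost their calls in fits without some single libraries (adjusted p of up to 0.128 without KO replicate 3 and 0.099 without WT replicate 3). The immediate-early genes Fos and Egr1, which respond to tissue handling, rose by log2 changes of 0.99 and 0.60 as the 2 called of 10 (adjusted p = 0.012 and 0.013), while the list did not pass camera (0.143). Adjusted over the list alone, 2 members were higher and 2 lower, Dusp1 among the latter. Without WT replicate 3 neither Fos nor Egr1 was called (adjusted p = 0.052 for each), and Egr1 also lost its call without KO replicate 2 (0.057) or 3 (0.053).

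**Figure D2:**
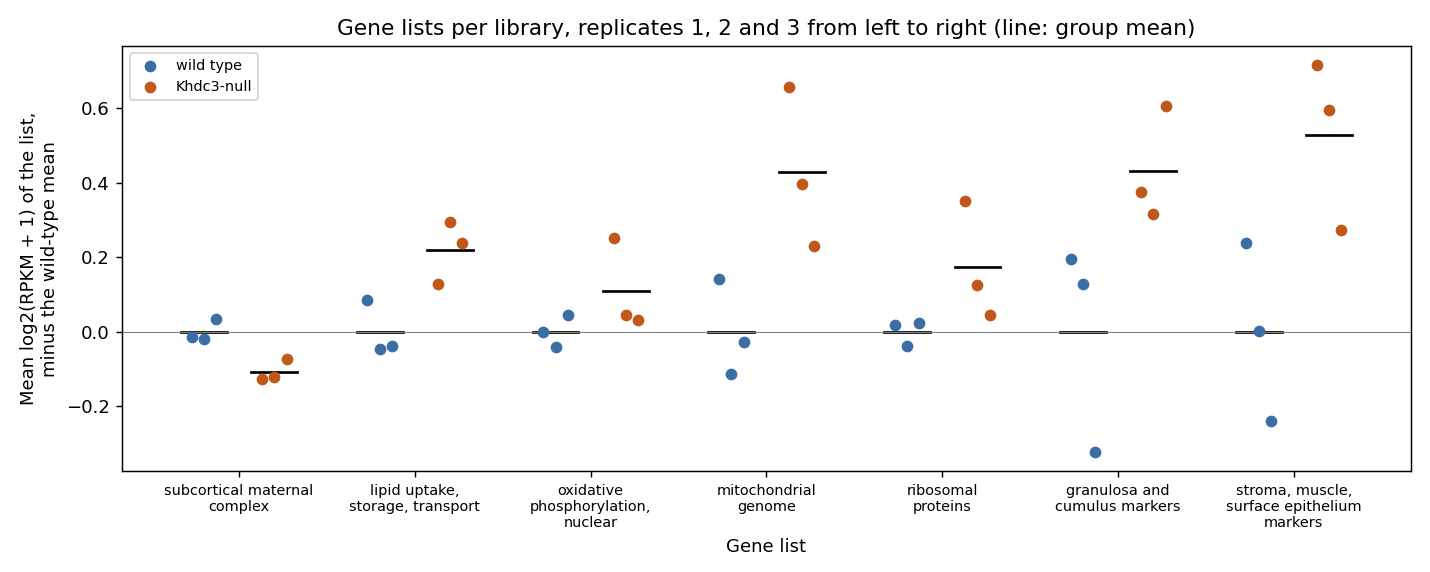
Mean log2(RPKM + 1) of 7 gene lists in each library, minus the wild-type mean of the list, for wild-type (blue) and Khdc3-null (orange) replicates, with lines at group means. KO replicate 1 is the highest library for the mitochondrial, ribosomal and oxidative phosphorylation lists, and all 3 KO libraries exceed all 3 WT libraries for the granulosa and the stromal markers.

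Called genes made up a larger share of tested genes around Khdc3 than elsewhere, and most of them lay in 1 group. Within 10 Mb on either side of the gene, 12 of 102 tested genes were called (11.8%), against 243 of 10182 elsewhere (2.39%), an odds ratio of 5.45 (95% confidence interval 2.68 to 10.2; Fisher's exact test, two-sided p = 7.8e-06). They included Usp3, at 66514637 to 66593142, and 9 of the 12 were higher in KO. Of the 12, 8 formed a single group from 65460947 to 67559703 (Spg21, Pif1, Rbpms2, Oaz2, Usp3, Aph1b, Tpm1 and Tln2, named here after their values were seen), and Fisher's test treats genes as independent, which genes called in groups are not. The odds ratio was 3.05 within 5 Mb (Fisher's exact p = 0.085), 3.62 with a 2-fold change also required (0.11) and 1.82 with no filter on low values (0.43). It was 1.39 without WT replicate 2, 2.75 without WT replicate 3 and 2.80 without KO replicate 3 (Fisher's exact p = 0.66, 0.10 and 0.10). The 17 tested genes of a list of chromosomal neighbours of Khdc3, fixed beforehand, held no called gene (camera adjusted p = 0.51). That list is not the set of nearest genes. Within 5 Mb of Khdc3 there were 42 tested genes, of which 3 were called.

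Called genes were also grouped elsewhere in the genome. Fisher's tests by chromosome again treat genes as independent, which genes called in groups are not, so their p-values may be too small. Chromosome 18 had the largest share outside the mitochondrial genome, with 28 of 277 tested genes called (10.1%; Fisher's exact test, adjusted p = 4.7e-09), and among chromosomes with a lower share than the rest the smallest p was that of chromosome 11, with 7 of 820 (0.854%; adjusted p = 0.0070). Of the 255 called genes with coordinates besides Khdc3, 125 had another called gene within 1 Mb, against a median of 81 and a highest value of 117 in 10000 random draws of as many tested genes (permutation p = 1e-04, one-sided, the smallest these draws can give). There were 19 groups of 3 or more called genes in which each lay within 1 Mb of the next, on 13 chromosomes with the mitochondrial genome counted as 1, and 15 of them held genes of both directions. The group with the most genes, 10, spanned chromosome 2 from 118814003 to 120461700 and held Exd1, Pla2g4e, Pla2g4f and Tmem87a. Of the 23 genes with the largest changes besides Khdc3, 20 had another called gene within 1 Mb.

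**Figure D3:**
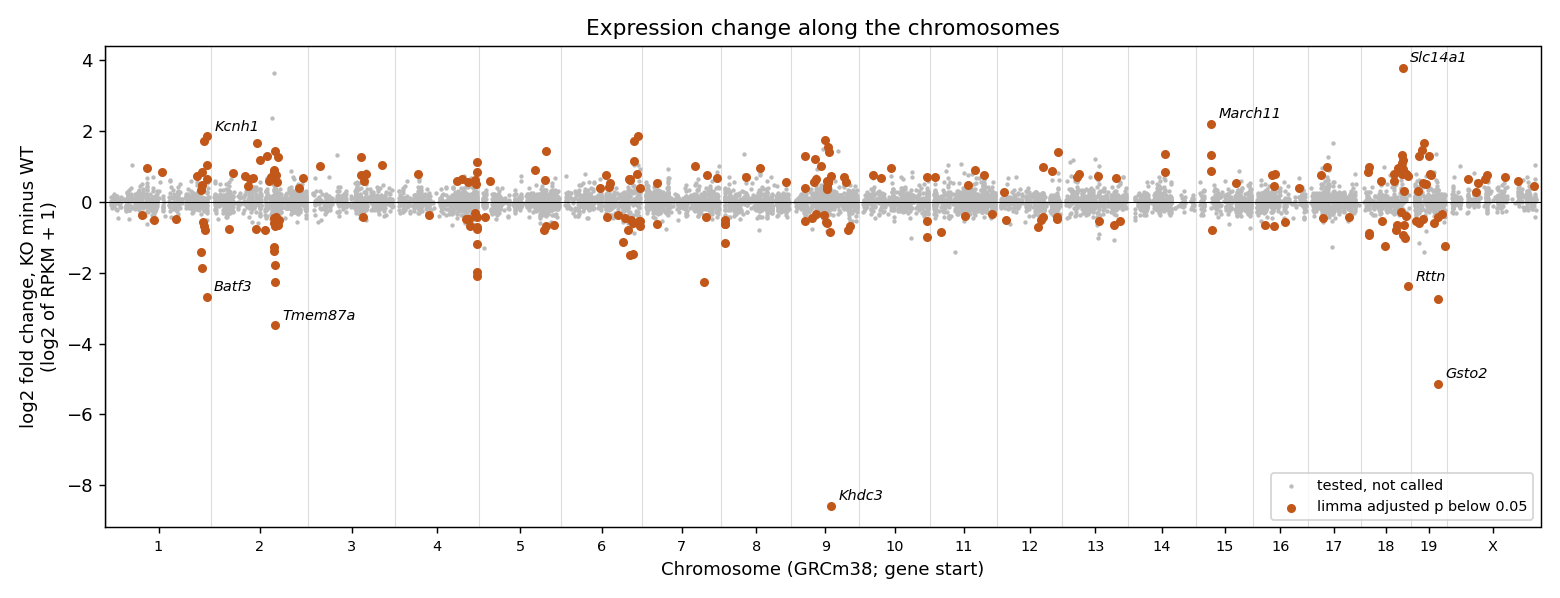
Change in expression (log2 of RPKM + 1, KO minus WT) of tested genes with coordinates, by start position on chromosomes 1 to 19 and X (GRCm38), in orange with a limma adjusted p below 0.05 and in grey otherwise. Called genes of both directions stand in narrow columns, as on chromosomes 1, 2, 4, 9 and 18.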

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

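Limma voom on the recovered reads was chosen after seeing the data, and the other alternatives were planned. The count of 336 called genes was 94 with no filter on low values, 222 with a filter of RPKM 5, 662 with library weights, 92 with a 2-fold change also required and 693 at an adjusted p under 0.1, and ranged from 151 to 289 with 1 library left out, where fewer samples enter the fit. The latter 2 thresholds change the count by construction. For the filters and weights the cause was not tested. Under the pseudocounts, rescalings and robust prior it was 311 to 356, and with voom 428, of which 308 were among the 336. With quantile normalization 183 were higher and 173 lower, and no rescaling moved the share of higher calls by over 10 percentage points. The Khdc3 change kept its direction and call in all 17 alternatives, from -11.27 with voom to -8.49, and from -8.61 to -8.49 with 1 library left out. The number of gene lists passing camera was 6, but 3 with a filter of RPKM 5, 0 with an estimated correlation and 0 with fry, and 4 to 9 with 1 library left out. The number of other-cell lists was 2, but 0 with the filter of RPKM 5, where fewer markers enter, and 1 to 3 with 1 library left out. The odds ratio near Khdc3 was 1.82 with no filter, 3.62 with a 2-fold change required, 3.05 with a window of 5 Mb, 3.36 with 20 Mb and 1.39 to 3.94 with 1 library left out, and 6 of its 21 alternatives missed the threshold. The cause was not tested, except that few genes were called inside the window (1 with no filter and 2 with a 2-fold change). With the replicate number as a block, 320 genes were called, 242 of them among the 336. The theca list then passed (camera adjusted p = 0.016, and 0.81 with an estimated correlation and no block). Of the named genes, 5 gained a call with the block, among them Nnat (limma adjusted p = 0.031) and Hspa8 (0.020), and 2 lost it, among them Nr5a1 (0.055). The correlations of same-numbered libraries' deviations from their group means were -0.02, 0.21 and -0.03, and only the libraries numbered 2 correlated best with their own number, a hint from the data and not from the design. Of 609 values for gene lists, 586 stayed on their side of the threshold, 10 lost the call and 13 gained it, and of 2810 for 150 named genes besides Khdc3, 2587 stayed, 148 lost it and 75 gained it. None turned direction with a call. Depth did not separate the groups. Genes near the filter of 1 RPKM rest on fewer reads than abundant ones, as with Nr5a1, on 160 to 196 reads in the WT libraries at a mean of 1.08 RPKM. In the simulated reads, 1.5-fold changes were found less often than 2-fold ones.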

Other observations

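Of the tests in this part, those of positions along chromosomes were chosen only after the result was seen. Several called genes of the spindle and centrosome, all chosen after their values were seen and not tested as a group, moved in both directions. Haus1 and Haus8, subunits of the augmin complex that nucleates microtubules within the spindle, stood at 33.9 ± 4.19 and 17.8 ± 2.04 RPKM in WT and at 80.2 ± 21.3 and 35.1 ± 1.31 RPKM in KO (SD, n = 3 each; limma adjusted p = 0.013 and 0.0018). The centrosomal kinase gene Nek2 rose from 28.2 ± 1.6 to 59.2 ± 3.31 RPKM (adjusted p = 3.1e-04). Nusap1, Knstrn and Hjurp, with roles in spindle, kinetochore and centromere assembly, fell by 0.60, 0.44 and 0.51 on the log2 scale (0.020, 0.040 and 0.020). Without some single libraries these 3 lost their calls, with adjusted p of up to 0.068, 0.127 and 0.082. Nusap1 and Knstrn lie in the chromosome 2 group of called genes. Haus1 lies in a group on chromosome 18 with Slc14a1, and Nek2 in a group on chromosome 1 with Batf3 and Kcnh1. The 41 genes of the spindle list fixed beforehand had a median log2 change of 0.02.

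Metabolic and signalling genes chosen after their values were seen included Angptl4, an inhibitor of lipoprotein lipase, at 0.956 ± 0.163 RPKM in WT and 2.89 ± 0.577 RPKM in KO, and Cyp7b1, an oxysterol hydroxylase, at 0.697 ± 0.0792 and 2.42 ± 0.255 RPKM (SD, n = 3 each; limma adjusted p = 0.012 and 0.0027). Acsbg1, Hao2 and Fabp7 had log2 changes of 1.02, 1.27 and 0.95. Esrrg, an orphan nuclear receptor, fell from 5.11 ± 0.462 to 2.53 ± 0.314 RPKM and Psen2, the presenilin 2 gene, from 45.6 ± 1.56 to 16.3 ± 1.49 RPKM (adjusted p = 0.010 and 9.7e-05). Gata6 and Fstl1, both expressed in ovarian somatic cells and chosen in the same way, had log2 changes of 0.84 and 0.79. Acsbg1, Hao2, Gata6 and Fstl1 lost their calls in some fits without 1 library, with adjusted p of up to 0.117, 0.062, 0.087 and 0.159. With all libraries, Fstl1 lost its call with pseudocounts of 0.1 (0.058) and 0.5 (0.052), and Fstl1 and Acsbg1 lost theirs when values were rescaled to the same total (0.057 and 0.052). With no filter on low values Haus1, Nusap1, Knstrn, Hjurp, Angptl4, Acsbg1, Hao2, Fabp7, Esrrg, Gata6 and Fstl1 lost theirs (adjusted p of 0.054 for Esrrg to 0.181 for Fstl1).

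Called genes lay in groups along the chromosomes. Chance placement was set aside by 125 called genes with another within 1 Mb, above the 117 reached in 10000 draws. The flank of the targeted gene alone was set aside by 110 without chromosome 9 (highest draw 106). Pairs of called genes 0.2 to 2 Mb apart numbered 208 (highest draw 129). This argues against sharing of reads or transcription between adjacent genes as the only source. Pairs closer than 0.2 Mb were not examined on their own, so such sharing is not excluded for them. A candidate explanation, offered as a hypothesis, is linked chromosome segments of differing genetic background that also vary between the WT libraries. The signed correlation of the 3 WT deviations averaged 0.264 over 460 pairs of called genes within 5 Mb (highest of 10000 reassignments 0.167), against 0.013 in the KO libraries. In WT it was 0.013 for genes not called. The direction of change of many of those genes may be noise, which shrinks a signed mean, so that value gives no level for neighbours in general. On chromosome 2, Spint1 and Dph6, not called in the main fit and chosen after their values were seen, stood at 27.1 and 14.8 RPKM in WT replicate 2, at 0.344, 0.322, 1.85 and 2.25 RPKM in WT replicates 1 and 3 and at 42.1 to 46.6 and 24.9 to 27.5 RPKM in KO, while Tmem87a was at 9.15 RPKM in WT replicate 2 and 17.6 and 18.1 RPKM in the others. The neighbours Gsto2 and Cfap58 on chromosome 19, called lower in KO, both stood highest in WT replicate 1 among the WT libraries. Spint1 and Dph6 were called without WT replicate 2 (limma adjusted p = 8.1e-07 and 1.6e-05) and with voom (0.038 and 0.028). The calls without WT replicate 2 restate how that library differed and are not separate support. Strain and breeding are not given in the sources used here and variants in the reads were not analysed here, so effects of Khdc3 loss and of background were not separated gene by gene and both stay open.

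Markers of granulosa and stromal cells lay higher in KO. More somatic cells in KO replicate 1 alone was argued against by the list medians without that library, 0.45 and 0.53. Somatic cells carried along with every KO library remain a candidate source, since 3 of 3 KO libraries exceeded all WT libraries on both lists. That separation is not particular to somatic markers. It was also seen in lists such as the imprinted, tricarboxylic acid cycle and unfolded protein response genes. The most abundant granulosa markers were Inha at 168 RPKM in WT and 260 in KO, Serpine2 at 85.9 and 88.4 and Esr2 at 35.3 and 30.5, and of the stromal markers Aldh1a2 at 41.1 and 32.2 (Serpine2, Esr2 and Aldh1a2 were chosen after their values were seen), while 6 of 20 and 2 of 14 markers had a WT mean of 10 RPKM or more, so oocyte expression of some is not excluded. A change in the oocytes' own expression of these genes stays open as well, untested.

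Ribosomal protein and mitochondrial transcripts lay higher in KO, and KO replicate 1 as the only source could be neither kept nor set aside. Without that library the median change of the ribosomal list was 0.416 of its value with all libraries and that of the mitochondrial list 0.715, so most of the first and the smaller part of the second rested on 1 library. What raised that library was not tested, and a difference between genotypes stays open for the rest.

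The 6 libraries can be divided in 10 ways into 3 and 3. The real division called 336 genes and the highest of the others 0, and 1 division of 10 reached the real count. With 10 divisions the share cannot fall under 0.05.

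On chromosome 19, Tmc1 and Ms4a6d were chosen after their values were seen and were not called in the main fit. Both were called with library weights (limma adjusted p = 0.0082 and 0.013) and without KO replicate 1 (0.0016 for each). These settings drop KO replicate 1 or give it the lowest weight, so the calls restate how that library differed and are not separate support. Tmc1 was also called with the replicate block (0.040) and with voom (0.039). They stood at 1.66 and 21.8 RPKM in KO replicate 1, at 0.0243 and 9.27 RPKM in KO replicate 2 and at 0.0283 and 6.80 RPKM in KO replicate 3. In WT replicates 1, 2 and 3, Tmc1 stood at 3.26, 2.26 and 2.73 RPKM and Ms4a6d at 25.0, 26.3 and 28.5 RPKM, so for these 2 genes KO replicate 1 lay nearer to WT than the other KO libraries did, and not all differences between libraries of a genotype were in WT.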
